A study of Mus musculus with 4 samples.

How the data were processed

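Total RNA of whole mouse colon, taken on day 5 of DSS, was measured on 4 one-colour arrays labelled with Cy3, 2 from Junb fl/fl control mice and 2 from Junb fl/fl Cd4-Cre mice. Groups and replicate numbers came from the sample titles and genotype labels. The deposited files are scanner output with linear spot intensity values, made with Agilent Feature Extraction 11.5.1.1 per the file headers and the submitters' processing notes. Per the file headers, the processed signal is the background-corrected intensity of each spot, and the mean signal and median background intensity are given beside it. No normalization between arrays is recorded there. The deposited flags, per the file headers, mark spots well above background, saturated spots and outliers, and were used as yes or no values.

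An array had 62976 spots, of which 59305 were not controls and represented 56605 probes. No spot was saturated. The 75th percentile of the intensity was 330 and 328.6 in the controls and 310.9 and 268.5 in the mutants. The precision is set by the number of arrays. The limma p-values measure the spread between 2 mice of each genotype, moderated by the spread of other genes (prior degrees of freedom 3.12). Camera p-values with a preset correlation set a list's genes against other genes. Their size reflects the spread over genes and not how far the difference would recur in other mice.

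The log2 of the processed signal was taken and each array's 75th percentile over its non-control spots was subtracted. Spots of a probe were averaged without spots marked as outliers, and 11 probes without a clean spot on every array were left out. Probes well above background on at least 2 of the 4 arrays were kept, and the probe with the highest mean represented its gene, which left 19325 genes. Of these, 6548 had several probes that passed the filter. Among 76 named genes tested, 20 had several such probes, and only those of Lpl disagreed in sign. Gene names are those of the array design. A current symbol was found for 15151 of the tested genes in a RefSeq table of assembly GRCm38.p6, which was used for names only. Probe coordinates are those of the files, on mm9.

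Differences are mutant minus control on the log2 scale, fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided, no block), and given with the moderated standard error, n = 2 and 2 arrays. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. A second count took genes at least 2-fold different with an unadjusted p under 0.05. Where a gene was not well above background on any array of a group, the fold is a bound, except for Il2ra, whose measured fold is given. Normexp correction with its offset shrinks differences of dim genes by construction. The bound sets the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among spots well above background and the gene's own signal. A single array not well above background was set to the same floor for the differences said to be so.

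A set of 34 gene lists (402 genes, of which 345 were tested) was fixed before the data were examined. It covered immune cells and pathways, epithelial, stromal and neural cells, neighbouring tissues, haemoglobin, sex-linked and housekeeping genes. Lists were tested with camera, two-sided, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 34 lists. Camera with an estimated correlation and fry were alternatives. Counts adjusted over the list alone used the genes of that list only. No list member passed the threshold adjusted over all genes.

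The genes named were set by a rule fixed in advance. It took Junb, Foxp3, Il2ra, Il2, Cd3e and Cd4 always, the 12 genes with the largest rise and the 12 with the largest fall past the adjusted threshold, and members of each list. Where fewer than 12 passed, places were filled by the largest differences at an unadjusted p under 0.05. From each list it took up to 4 members past the threshold over all genes or over the list alone, and otherwise up to 3 by smallest p. Genes without a symbol were not named. Names of the form of sequence accessions were counted among these after the data were seen. Genes outside the rule are said to be so.

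The fits were also run on simulated data. Arrays were simulated for 19325 independent genes, with the mean signals of the controls and variances drawn from the fitted prior, with 200 genes changed, in 5 runs. For log2 changes of 1, 2, 3 and 4 the fit without a block called 14.8%, 71.6%, 85.6% and 92.8% at the adjusted threshold, and 5 unchanged genes per run. Camera with the preset correlation called a list shifted by -0.5 in 10 of 10 runs, and 1 of 330 unshifted lists. With an estimated correlation it called the shifted list in 0 of 10 runs, with adjusted p at or above 0.462, and fry called it in 4 of 10. As these genes were independent, the runs do not show how the preset setting fares with correlated genes.

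The alternatives fixed in advance were normexp background correction with an offset of 50, quantile normalization, no filter on dim probes, a filter on all 4 arrays, no intensity trend, and the mean of a gene's probes. Others were a block by replicate number, every probe tested separately, and leaving out each array in turn. A block by sex, crossed pairs and the other splits of the arrays were added after the data were seen. A block by slide or scan was not run, as there was 1 slide and 1 scan.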

Results

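RNA of the whole colon of C57BL/6 mice was hybridised to 4 one-colour Agilent arrays. Control mice carried floxed Junb alleles without Cre, and the mutant mice carried the same alleles with Cd4-Cre, which deletes floxed DNA in cells of the T cell lineage. JunB is a transcription factor of the AP-1 family. All mice had been given dextran sulphate sodium (DSS), which injures the colon epithelium and brings on colitis, and the tissue was taken on day 5. Each genotype had 2 arrays. Between 27935 and 29090 of 56605 probes lay well above background on an array, and no spot was saturated. The arrays correlated with Pearson's r between 0.976 and 0.984 across 19325 genes and did not group by genotype. The lowest r was between the 2 controls, and the highest between control replicate 2 and mutant replicate 2. The 2 mutants had 0.982. The number of arrays limits the precision of every value below.

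The labels do not state the sex of the mice. Xist, transcribed from the inactive X chromosome, and the Y-linked gene Eif2s3y separated replicate 1 from replicate 2 in both genotypes. The log2 signal of Xist was -0.55 and -0.77 on the replicate 1 arrays of control and mutant, and -6.13 and -6.43 on the replicate 2 arrays. Eif2s3y gave -6.08 and -6.20 on the replicate 1 arrays against 0.20 and -0.11 on the replicate 2 arrays. Each genotype was therefore 1 female and 1 male colon, from separate mice. Differences within the female pair and within the male pair are given beside the pooled values, and fits with sex as a block were added after the data were seen.

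The targeted gene was measured first. The brighter Junb probe (chromosome 8, 87500843 to 87500902, mm9) had a log2 signal of 4.23 and 4.39 in the controls and 4.44 and 4.47 in the mutants. Junb was 1.11-fold higher in the mutants (log2 difference 0.15 ± 0.11, SE, limma adjusted p = 0.691), a difference that did not pass the test. A dimmer Junb probe, well above background on all 4 arrays, gave 0.13 ± 0.34, and the third probe was not well above background on any array. Cd4-Cre leaves Junb intact outside the T cell lineage, so whole tissue is no check of the deletion. Foxp3, the transcription factor of regulatory T cells, was not well above background on any array. A probe of Il2 was well above background on 1 array only. Il2ra, the high-affinity subunit of the IL-2 receptor, was well above background in both controls and in neither mutant. Its measured signal was 1.72-fold lower in the mutants (adjusted p = 0.547). The floor did not change this difference, so the fold is not a bound. That difference was -0.07 after normexp background correction. Another Il2ra probe, not well above background on any array, went the other way, at -5.32 and -5.97 in the controls and -4.01 and -4.29 in the mutants. Cd3e differed by -0.32 ± 0.16 and Cd4 by -0.03 ± 0.14 on the log2 scale, and neither passed the test. Without 1 array Cd3e ranged from -0.47 to -0.18 (without control replicate 2 and control replicate 1), and its other probe gave -0.15. Another Cd4 probe, well above background on 1 array only, lay at -5.74 and 1.43 in the controls and -6.28 and -4.53 in the mutants. A further Cd4 probe was not well above background on any array.

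The comparison asked how the colon transcriptome of the mutant mice, described by the submitters as having more severe DSS colitis, differed from that of the controls. Among gene lists fixed before the data were examined, inflammatory cytokines, chemokines, neutrophil genes, antimicrobial epithelial genes and cell cycle genes rose in the mutant colon by camera with a preset correlation between genes of 0.01, and T cell, smooth muscle, enteroendocrine, adipocyte and haemoglobin genes fell. All these calls were lost with an estimated correlation (adjusted p = 0.404 to 0.460), and fry called no list in a direction (smallest adjusted p = 0.104). In simulated arrays, the estimated correlation called a list shifted by -0.5 in 0 of 10 runs, and fry in 4 of 10. A call lost in these settings therefore does not show that a list was unshifted. Reg3g, an antibacterial lectin of the gut epithelium, was 6.25-fold higher (log2 difference 2.64 ± 0.29, SE), and Ifng, the cytokine interferon gamma, differed by 1.85 ± 0.32, against the direction of the list that holds it. No single gene passed the adjusted threshold without a block, so the statements on groups rest on the tests of lists, and those on Reg3g and Ifng on unadjusted p or adjustment over a list alone. Camera with the preset correlation called 14 of 34 lists, 7 higher and 7 lower.

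No gene of 19325 passed an adjusted p of 0.05 in limma without a block, and the smallest adjusted p was 0.373. At an unadjusted p under 0.05 there were 1796 genes, where 966 would be expected with no effect. The same threshold gave 1658 genes for the female against the male arrays and 169 for the remaining split, which mixes genotype and sex. The second count fixed in advance, at least 2-fold and unadjusted p under 0.05, gave 263 genes, 139 higher and 124 lower. It is not corrected for multiple tests, and 182 of 19125 unchanged genes met it on average in simulated arrays of this design. With normexp background correction it gave 85 genes, 56 higher and 29 lower, without the filter on dim probes 571, and with a filter on all 4 arrays 156. Without control replicate 1, control replicate 2 or mutant replicate 2 it gave 436, 500 and 447. With sex as a block, 46 genes passed the adjusted threshold, 35 higher and 11 lower. In simulated arrays, which held 200 changed genes and no effect of sex, the blocked fit called 10.2 unchanged genes per run on average. That value is no estimate of the false calls among the 46.

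The inflammatory cytokine list rose, with a median log2 difference of 1.07 over 9 measured genes (1.31 in the female pair, 0.93 in the male pair, camera adjusted p = 3.56e-05). Within the list, 5 genes were higher and none lower, adjusted over the list alone. They included Il6 (1.95 ± 0.59), the T cell and myeloid cytokine Osm (1.70 ± 0.32), Il1b (1.66 ± 0.32) and Nos2, the inducible nitric oxide synthase (1.07 ± 0.28). Il6 differed by 1.25 without mutant replicate 2, and Nos2 by 0.68 without mutant replicate 1. Il6 did not pass the unadjusted threshold without control replicate 1 or mutant replicate 2, nor Nos2 without control replicate 2. The chemokine list rose as well, with a median of 0.88 over 18 genes (0.93 in the female pair, 0.59 in the male pair, adjusted p = 0.00146). The median was 0.56 without control replicate 1 and 0.49 after normexp correction, and 0.69 with dim genes at the floor. Of its genes, 13 were higher and 5 lower, and 6 were higher and none lower adjusted over the list alone. The interferon-induced T cell attractants Cxcl9 (2.10 ± 0.23) and Cxcl10 (1.28 ± 0.19) were among them, as were Ccl4 (1.18 ± 0.14) and the neutrophil attractant Cxcl2, which was at least 2.37-fold higher and well above background in the mutants only. With an estimated correlation, the adjusted p of the cytokine list was 0.404 and that of the chemokine list 0.460.

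Of 10 neutrophil genes measured, 7 were higher and 3 lower (median 1.34, with 1.33 in the female pair and 1.53 in the male pair, adjusted p = 0.0213). Only Ltf, encoding lactoferrin, passed adjusted over the list alone (1.48 ± 0.26). The calprotectin genes S100a8 (2.24 ± 0.78) and S100a9 (2.24 ± 0.88) had adjusted p = 0.0409 and 0.0237 with sex as a block, and did not pass without it. The list's adjusted p was 0.410 with an estimated correlation. Its median was 0.39 without control replicate 1 (adjusted p = 0.0997), 0.62 without mutant replicate 2 and 0.80 after normexp correction. Without the same 2 arrays in turn, S100a8 differed by 1.49 and 1.25 and S100a9 by 1.23 and 1.29, none past the unadjusted threshold. Antimicrobial epithelial genes rose (12 of 14 higher, median 0.27, with 0.40 in the female pair and 0.25 in the male pair, adjusted p = 0.000384). Reg3g and its relative Reg3b (1.45 ± 0.28) passed adjusted over the list alone. The estimated correlation gave this list an adjusted p of 0.404, and its median was 0.16 after quantile normalization.

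**Figure D1:**
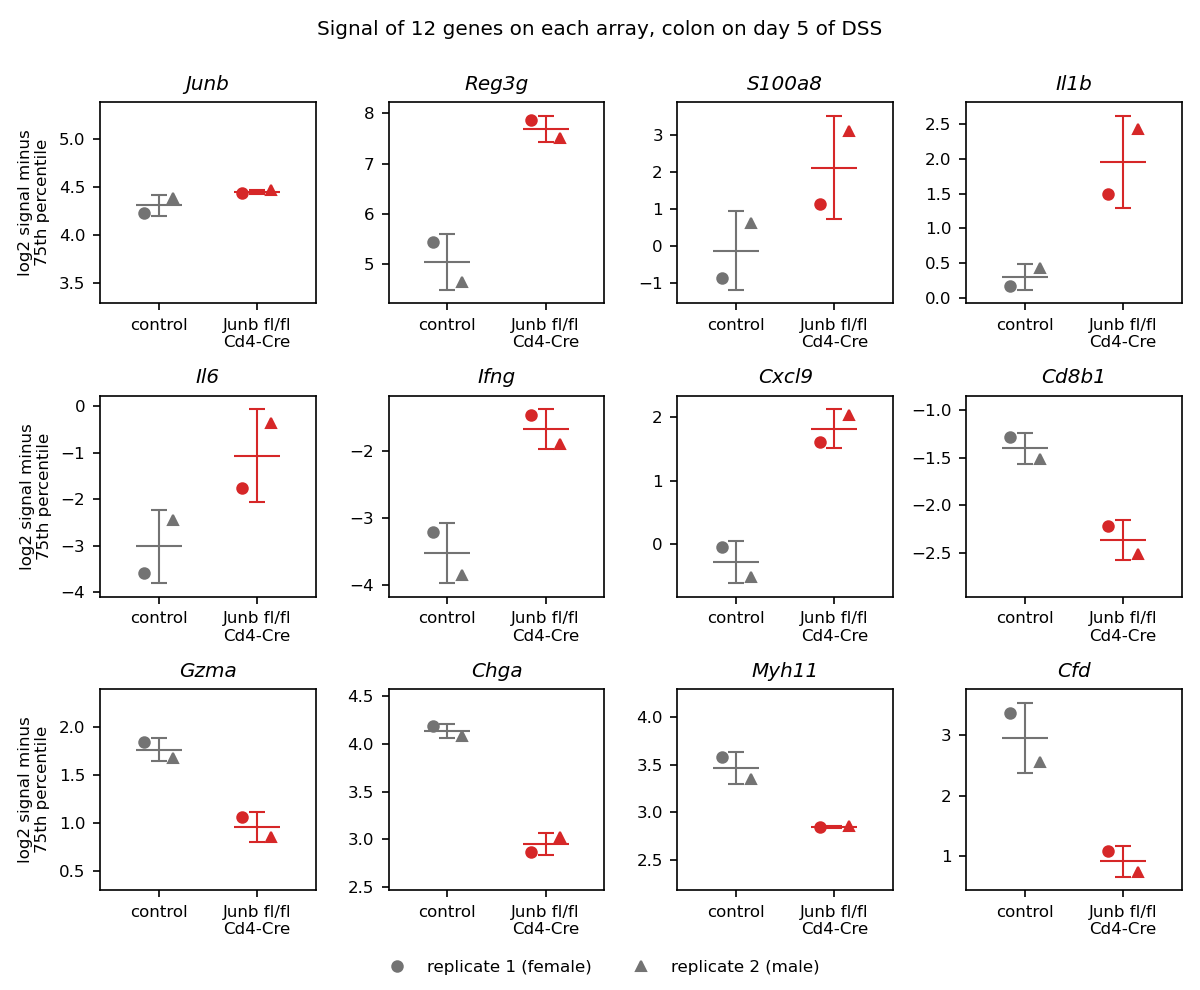
Log2 signal minus the array's 75th percentile for 12 genes in control (grey) and Junb fl/fl Cd4-Cre colon (red), with 1 panel per gene. Circles are replicate 1 (female), triangles replicate 2 (male), horizontal lines the mean and error bars the SD of 2 arrays. Junb lies between 4.23 and 4.47 on the 4 arrays, while Reg3g lies at 5.44 and 4.66 in the controls and at 7.88 and 7.51 in the mutants.

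Cell cycle genes rose together. All 16 members of the proliferation list were higher in both the female and the male pair (median 0.79, with 0.97 and 0.62 in the pairs, adjusted p = 7.92e-12), and 13 passed adjusted over the list alone. The mitotic genes Plk1 (0.92 ± 0.20), Ube2c (0.92 ± 0.17) and Birc5 (0.92 ± 0.19) and the cyclin gene Ccna2 (0.85 ± 0.20) had the largest differences. Crypt stem cell genes had a median of 0.29 (0.27 in the female pair, 0.17 in the male pair), with 9 of 10 higher and an adjusted p of 0.0167. None passed adjusted over the list alone, and the stem cell marker Lgr5 differed by 1.70 ± 0.48, not past the unadjusted threshold without control replicate 2 or mutant replicate 1. That call was lost without control replicate 2 (adjusted p = 0.0612) and without mutant replicate 1 (0.0680). With an estimated correlation, both lists had an adjusted p of 0.410.

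T cell genes fell: 16 of 17 were lower, with a median of -0.41 (-0.53 in the female pair, -0.41 in the male pair, adjusted p = 8.6e-10). Adjusted over the list alone 5 were lower. The co-receptor gene Cd8a was at least 2.71-fold lower and not well above background in the mutants, Cd8b1 differed by -0.96 ± 0.21, the signalling adaptor Lat by -0.88 ± 0.19 and the surface receptor gene Cd6 by -0.85 ± 0.14. The type 1 and cytotoxic list fell too (9 of 11 lower, median -0.36, with -0.46 in the female pair and -0.14 in the male pair, adjusted p = 0.0264). Its members parted: the granzyme genes Gzma (-0.81 ± 0.14) and Gzmb (-0.73 ± 0.19) were lower and Ifng was higher, each past the threshold adjusted over the list alone. Without control replicate 2 or mutant replicate 1, Gzmb did not pass the unadjusted threshold. The estimated correlation gave adjusted p values of 0.404 and 0.410 to these lists. The call of the cytotoxic list was also lost after normexp correction (adjusted p = 0.0581), after quantile normalization (0.122) and without the filter on dim probes (0.422), and it was lost without control replicate 1, control replicate 2 or mutant replicate 2, with adjusted p values of 0.116, 0.0546 and 0.0622. Its median was -0.60 without control replicate 2 and -0.20 after normexp correction.

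The regulatory T cell list did not pass (7 of 11 measured genes lower, median -0.20, with -0.05 in the female pair and -0.22 in the male pair, adjusted p = 0.0557). Itgae, encoding the integrin CD103 of intraepithelial and regulatory T cells, had the smallest p in it, at a difference of -0.52 ± 0.19. Of the list's 18 fixed genes 11 were tested. Foxp3 was not among them, nor were Ctla4 and Il10, which lie outside the naming rule. The list passed without control replicate 1 (median -0.29, adjusted p = 0.0308), without mutant replicate 1 (-0.10, 0.0499) and without the intensity trend (0.0407). Its median was -0.11 without control replicate 2 and -0.07 after normexp correction. The list of IL-2 and STAT5 signalling did not pass (8 of 16 higher, adjusted p = 0.101), but did so without mutant replicate 1 (0.0492), without the filter on dim probes (0.00326) and with a filter on all 4 arrays (0.0358). Adjusted over the list alone, 3 of its genes were higher: Osm and the cytokine-induced inhibitors Socs1 (1.26 ± 0.21) and Socs3 (1.07 ± 0.11). The interferon-stimulated list did not pass either (10 of 19 higher, adjusted p = 0.574, and 0.0263 without mutant replicate 2). Adjusted over the list alone, Cxcl10 and the guanosine triphosphatase genes Iigp1 (1.57 ± 0.36) and Irgm1 (0.58 ± 0.11) were higher. Another Iigp1 probe gave 0.76 and did not pass the unadjusted threshold. Ifit3 (-0.51 ± 0.13) was lower adjusted over the list alone, though it did not pass the unadjusted threshold without mutant replicate 2.

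Smooth muscle genes fell, and all 10 were lower in both pairs (median -0.59, with -0.48 in the female pair and -0.59 in the male pair, adjusted p = 7.92e-12). There were 9 lower adjusted over the list alone, among them Synpo2 (-0.75 ± 0.16), Des (-0.66 ± 0.12), Actg2 (-0.65 ± 0.15) and the smooth muscle myosin gene Myh11 (-0.61 ± 0.12). Adipocyte genes fell as well (6 of 7 lower, median -0.77, with -0.89 in the female pair and -0.90 in the male pair, adjusted p = 3.56e-05). The secreted products Adipoq (-2.24 ± 0.49) and Cfd (-2.04 ± 0.30) and the lipase Lpl (-0.77 ± 0.14) passed adjusted over the list alone. The 5 probes of Lpl ranged from -0.77 to 0.05. All 4 red blood cell genes were lower (median -1.32, with -1.44 and -1.20 in the pairs, adjusted p = 0.00148), including Hbb-b1 (-1.61 ± 0.51) and Hba-a1 (-1.24 ± 0.44), and the call was lost without control replicate 2 (median -0.82, adjusted p = 0.0565) and without the filter on dim probes (0.0845). Without mutant replicate 1 the median was -0.70, and without mutant replicate 2 it was -1.96. Hbb-b1 ranged from -2.29 to -0.93 and Hba-a1 from -1.80 to -0.69 without 1 array, and neither passed the unadjusted threshold without control replicate 2 or mutant replicate 1. Enteric neuron and glia genes had a median of -0.21 (-0.37 in the female pair, -0.10 in the male pair, adjusted p = 0.0235), with Ret at -0.51 ± 0.16 and S100b at -0.54 ± 0.18, neither past the unadjusted threshold without mutant replicate 1 or mutant replicate 2, nor Ret without control replicate 1 and S100b without control replicate 2. That call was lost without control replicate 1, control replicate 2 or mutant replicate 1, at adjusted p = 0.0888, 0.0548 and 0.441, and after quantile normalization (0.0565) or without the filter on dim probes (0.629). Its median was -0.14 without mutant replicate 1, -0.43 without mutant replicate 2 and -0.10 after normexp correction. The estimated correlation gave adjusted p values of 0.404 for smooth muscle and adipocytes, 0.452 for red blood cells and 0.599 for neurons and glia.

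Enteroendocrine cell genes fell, and all 10 were lower in both pairs (median -0.76, with -0.61 in the female pair and -0.86 in the male pair, adjusted p = 5.25e-10). Of these, 7 were lower adjusted over the list alone. Chga (-1.18 ± 0.11) and Chgb (-1.09 ± 0.14) encode proteins of secretory granules, and Insl5 (-1.32 ± 0.33) and Pyy (-0.87 ± 0.17) encode hormones of the distal gut. The adjusted p was 0.404 with an estimated correlation. Within the female and the male pair, Chga differed by -1.32 and -1.05, Insl5 by -0.66 and -1.97 and Pyy by -0.55 and -1.18, and Insl5 differed by -0.84 without mutant replicate 2. Distal colon Hox genes, which mark the stretch of colon, were lower in 5 of 5 cases as well (median -0.89, with -0.23 in the female pair and -1.96 in the male pair, and -0.59 with dim genes at the floor). That median was -2.35 without mutant replicate 1 and 0.26 without mutant replicate 2, so its direction rested on 1 mutant array. The goblet cell list did not pass (8 of 10 lower, adjusted p = 0.0793), but did so after quantile normalization (3.72e-05), after normexp correction (0.0194), and without control replicate 1 (0.0229) or mutant replicate 2 (0.0083). Fcgbp, a component of mucus, was lower adjusted over the list alone (-0.62 ± 0.12). The housekeeping list was higher by a median of 0.17 (0.15 in the female pair, 0.12 in the male pair, adjusted p = 0.0203, and 0.410 with an estimated correlation), with Ppia at 0.27 ± 0.10. Its adjusted p was 0.547 after quantile normalization and 0.0581 after normexp background correction. Without control replicate 1, control replicate 2 or mutant replicate 2 it was 0.0679, 0.0612 and 0.0823. The median of all genes was 0.02.

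**Figure D2:**
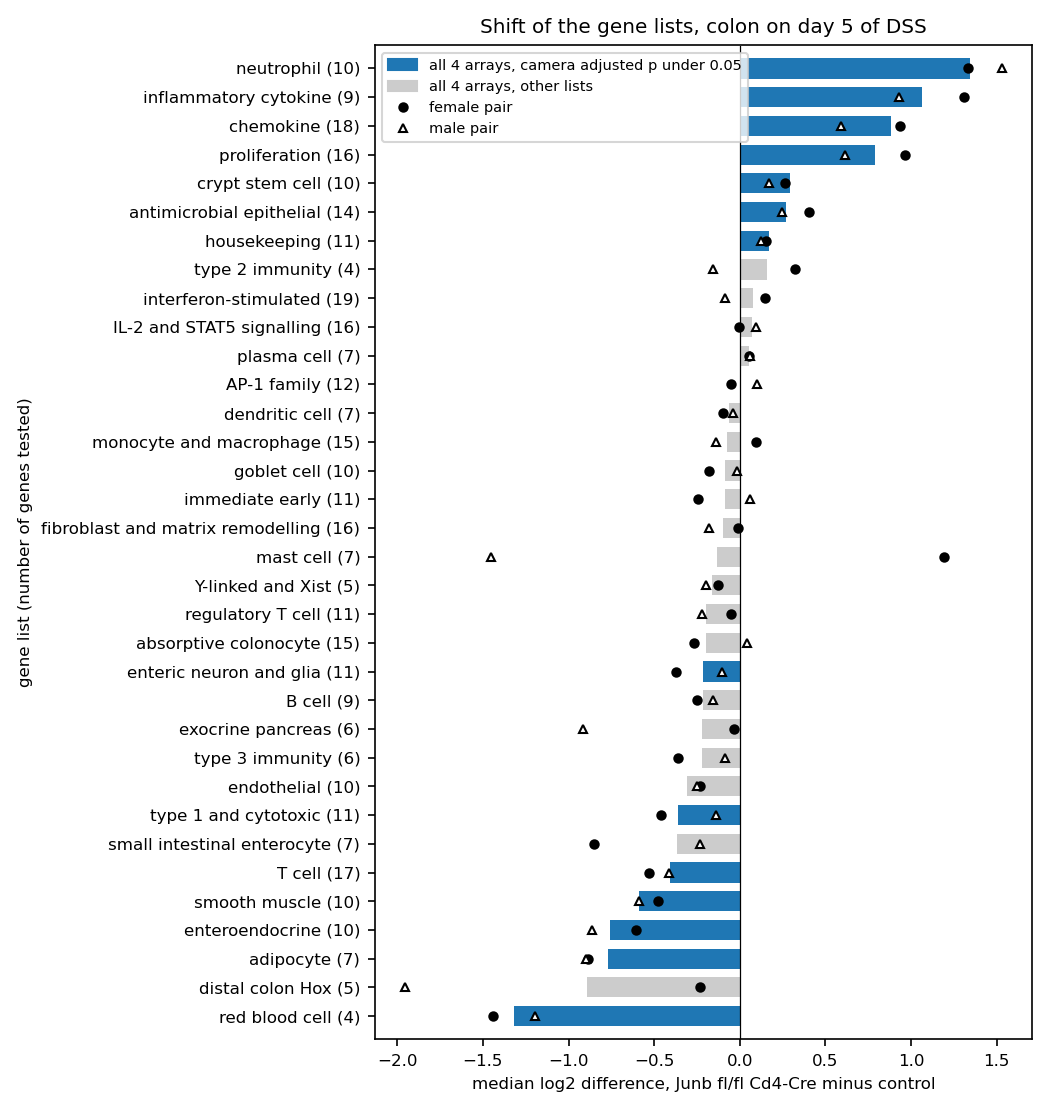
Median log2 difference of each of the 34 gene lists between Junb fl/fl Cd4-Cre and control colon, with the number of genes tested in parentheses. Bars are the median over all 4 arrays, blue where camera gave an adjusted p under 0.05. Filled circles are the female pair and open triangles the male pair. The neutrophil list lies at 1.34 and the red blood cell list at -1.32, and the mast cell list lies at 1.19 in the female pair and at -1.45 in the male pair.

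The other lists did not pass without a block. Their adjusted p values were 0.127 for type 3 immunity, 0.990 for type 2 immunity, 0.823 for monocytes and macrophages, 0.248 for dendritic cells, 0.0621 for B cells and 0.433 for plasma cells. They were 0.403 for mast cells, 0.16 for absorptive colonocytes, 0.470 for fibroblasts and matrix remodelling, and 0.199 for endothelium. Of the fixed genes, 6 of 12 for type 3 and 4 of 9 for type 2 immunity were tested. Il17a, Il17f, Il4, Il5 and Il13, outside the naming rule, did not pass the filter on signal. The tests of these lists therefore leave out those cytokines. Among monocyte genes, Cd14 was higher adjusted over the list alone (0.70 ± 0.10), and among endothelial genes the adhesion molecule Icam1 was (0.84 ± 0.16). Exocrine pancreas, small intestinal enterocyte and distal colon Hox genes each had an adjusted p of 0.0557. Leaving out 1 array brought some of these lists past the threshold. Without control replicate 1 they were monocytes (0.00432), mast cells (0.000284), fibroblasts (0.000507), endothelium (0.0052) and pancreas (0.00419), and without control replicate 2 B cells (0.0226) and enterocytes (0.033). Without mutant replicate 1 they were B cells (0.0449), pancreas (0.0449) and Hox genes (1.2e-07). Without mutant replicate 2 they were colonocytes (0.0164), fibroblasts (0.0379), endothelium (0.0205), enterocytes (0.0083) and immediate early genes (0.0182). The fibroblast list had a median of -0.10 and a mean of 0.18, and the AP-1 list a median of 0.01 and a mean of -0.06, with both tests in the lower direction. The AP-1 family, to which Junb belongs, had 0.784, immediate early genes 0.288, and Y-linked genes with Xist 0.868.

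The genes with the largest differences were named by a fixed rule and, without a block, none passed the threshold adjusted over all genes. They passed the unadjusted threshold, and Reg3g, Cxcl9 and Amy2a5 also passed adjusted over their list alone. With sex as a block, Reg3g, Bcl2l15 and S100a9 (adjusted p = 0.0237), S100a8 (0.0409) and Clec4e and Vmn1r188 (0.0460) passed the adjusted threshold. Among the 12 with the largest rise were Reg3g, S100a8, S100a9 and Cxcl9. Others were the myeloid receptor gene Clec4e (4.44-fold higher) and Bcl2l15, a member of the Bcl-2 family (9.60-fold higher). Without 1 array, Clec4e ranged from 1.507 to 2.795 on the log2 scale. Ptx3, a soluble pattern recognition molecule, was at least 2.27-fold higher, since it was not well above background in the controls. The same held for Ccdc148 (at least 2.67-fold), the gastric mucosal gene Gkn1 (at least 1.75-fold) and Teddm1b (at least 1.61-fold). Without mutant replicate 1 the bound of Ptx3 was 1.27-fold, and Teddm1b did not pass the unadjusted threshold. Sapcd1 and Pdzd9 were well above background on 1 control array only, and with the other control set to the floor each was higher by at least 2.39 on the log2 scale. Without mutant replicate 2 the bound was 1.73 for Pdzd9 and 1.995 for Sapcd1, and Sapcd1 differed by 2.10 without control replicate 2.

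Among the 12 genes with the largest fall, 10 were not well above background in either mutant, and the folds given for them are bounds. Most of these bounds moved by over 1.5 times without 1 control, so the lowest bound without 1 array is given beside each. The vomeronasal and olfactory receptor gene bounds were at least 5.31-fold lower for Vmn1r188 (3.70-fold without control replicate 1), 4.48-fold for Olfr635 (1.95-fold without control replicate 1) and 2.89-fold for Vmn2r62 (1.66-fold without control replicate 2). Without control replicate 1, the sensory neuron receptor gene Mrgprb4 went from at least 3.31-fold to 2.07-fold lower and the pancreatic amylase gene Amy2a5 from 3.29-fold to 1.75-fold. Without control replicate 2, Fgf2os went from at least 2.79-fold to 1.71-fold lower and the extracellular protease gene Adamts12 from 2.72-fold to 2.08-fold. The metalloproteinase inhibitor gene Timp4 was at least 4.12-fold lower (1.74-fold without control replicate 2), Crisp3 3.73-fold (1.75-fold without control replicate 2) and Plxdc1 3.13-fold (1.53-fold without control replicate 1). These 3 did not pass the unadjusted threshold after normexp correction. Nor did Timp4 without control replicate 2 or mutant replicate 2, Crisp3 without mutant replicate 2, or Plxdc1 without either replicate 1 array. Cyp2e1, a cytochrome P450, was 5.44-fold lower (-2.44 ± 0.37) and Gdap1 differed by -2.44 ± 0.90, both well above background on all 4 arrays. Gdap1 lay at -3.84 without control replicate 1 and at -1.04 without control replicate 2, and did not pass the unadjusted threshold without either mutant array, after normexp correction (-1.22) or quantile normalization, without the filter on dim probes or without the intensity trend. Within the female and the male pair, Bcl2l15 differed by 3.20 and 3.33 and Reg3g by 2.43 and 2.86, while Gdap1 differed by -0.95 and -3.94.

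With sex as a block and the preset correlation, all 14 lists stayed past the adjusted threshold, with adjusted p between 5.52e-11 and 0.0381. In all 20 lists passed. The other 6 were B cells (0.0442), absorptive colonocytes (0.0399), goblet cells (0.0442), exocrine pancreas (0.0205), small intestinal enterocytes (0.00648) and distal colon Hox genes (0.0077). An estimated correlation was not tried with the block. Without a block it gave these 6 lists camera adjusted p between 0.410 and 0.644. All 4 arrays lay on 1 slide and came from 1 scan, so position on the slide and genotype cannot be told apart.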

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

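The tests of sex were chosen after the data were seen. Each result here differed in direction between the female and the male pair, with 1 mouse of each genotype per sex, so the difference was not tested and no explanation is offered. The mast cell list differed most. Its median was 1.19 in the female pair and -1.45 in the male pair, a gap of 2.64 on the log2 scale. The mast cell protease gene Mcpt1, chosen after its values were seen, differed by 1.46 in the female pair and by -1.58 in the male pair, a gap of 3.04. Its log2 signal was -2.13 and 1.34 in the female and male control and -0.68 and -0.24 in the mutants, so the controls lay apart. The other gaps, female minus male, were under 0.5. They were 0.48 for type 2 immunity, 0.24 for monocytes and macrophages, 0.23 for interferon-stimulated genes, -0.10 for IL-2 and STAT5 signalling, -0.31 for absorptive colonocytes, -0.15 for the AP-1 family, -0.30 for immediate early genes and -0.25 for Cd4.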

How the results depend on the processing

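Signal over background limits the dim probes, and 2 arrays per genotype limit every p. Fits without an array pool the spread and assume that the lone array varies like the others. A block by slide or scan was not run, as there was 1 of each. Except where a value shows it, the cause was not tested.

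No gene passed the adjusted threshold under normexp correction, quantile normalization, no filter, a filter on all 4 arrays, no trend, the mean of a gene's probes, every probe tested separately, or without any 1 array. With a replicate block, the pairing by number gave 46 genes, and so did the sex block, which is the same fit here. The numbers are not stated to pair mice, and deviations of same-numbered arrays correlated with r = 0.239 (0.222 without X and Y probes). The count of 263 genes at least 2-fold different became 85 with normexp (56 higher and 29 lower, against 139 and 124), 571 without the filter, where more genes were tested, 156 with a filter on all 4 arrays, and 340 to 500 without 1 array. Other settings stayed within 1.5 times it. Junb passed under no setting.

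With an estimated correlation 0 lists passed against 14. The adjusted p was 0.404 for T cell, inflammatory cytokine, antimicrobial, enteroendocrine, smooth muscle and adipocyte lists, 0.410 for type 1 and cytotoxic, neutrophil, crypt stem cell, proliferation and housekeeping lists, 0.460 for chemokines, 0.452 for red blood cells and 0.599 for enteric neurons and glia. The estimated correlation was 0.989 for red blood cells, 0.584 for proliferation, 0.357 for smooth muscle and 0.244 for chemokines, against the preset 0.01. It was 0.474 for enteric neurons and glia, 0.180 for T cells, 0.045 for type 1 and cytotoxic genes and 0.044 for neutrophils. It lay below the preset for enteroendocrine (0.0006), inflammatory cytokine (-0.0177), antimicrobial (-0.0281), adipocyte (-0.029), housekeeping (-0.0601) and crypt stem cell genes (-0.0794), whose calls were lost as well. In simulated arrays of independent genes this setting called the shifted list in 0 of 10 runs. The loss of a call therefore does not show that correlation between genes undid it. Simulated genes were independent, so how often the preset setting calls unshifted lists of correlated genes was not tested. With fry 0 lists passed in a direction. Its mixed test, which asks whether genes of a list differ in either direction, gave an adjusted p under 0.05 to 10 lists: IL-2 and STAT5 signalling (5.31e-06), type 1 and cytotoxic, exocrine pancreas and housekeeping (0.0187), chemokine, enteroendocrine and adipocyte (0.0194), antimicrobial (0.0226), and T cell and smooth muscle (0.0367). It does not compare a list with other genes. The directional adjusted p was 0.104 for T cell, inflammatory cytokine, antimicrobial, enteroendocrine, smooth muscle, adipocyte and housekeeping lists, 0.258 for type 1 and cytotoxic, 0.280 for neutrophils and chemokines, 0.251 for crypt stem cells and proliferation, 0.526 for enteric neurons and glia and 0.437 for red blood cells. Splits of the arrays added after the data were seen gave 9 lists (female against male) and 4 (the remaining split) with the preset correlation. The smallest camera adjusted p was 1.1e-07 in the first (fibroblasts and matrix remodelling) and 0.00271 in the second (immediate early genes). Of the 14 lists, chemokines passed in the first (adjusted p = 0.0272), and proliferation (0.0177) and enteric neurons and glia (0.037) in the second, so these calls also arose where each side held both genotypes.

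With the preset correlation, 8 of the 14 lists stayed past the threshold in all 11 alternatives: T cell, inflammatory cytokine, chemokine, antimicrobial, enteroendocrine, proliferation, smooth muscle and adipocyte. Normexp gave an adjusted p of 0.0581 to the type 1 and cytotoxic list and 0.0581 to the housekeeping list. Quantile normalization gave 0.122 for type 1 and cytotoxic, 0.0565 for enteric neurons and glia and 0.547 for housekeeping. Without the filter, type 1 and cytotoxic had 0.422, enteric neurons and glia 0.629 and red blood cells 0.0845. Without 1 array, ranges were 0.0227 to 0.116 for type 1 and cytotoxic, 9.43e-05 to 0.0997 for neutrophils, 0.00261 to 0.0680 for crypt stem cells, 0.00165 to 0.441 for enteric neurons and glia, 3.4e-06 to 0.0565 for red blood cells and 0.0492 to 0.0823 for housekeeping.

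Some lists that had not passed did so in other settings, and those without 1 array or with the block are named above. After normexp goblet cells passed (0.0194), and after quantile normalization goblet cells (3.72e-05) and colonocytes (0.005). IL-2 and STAT5 signalling passed without the filter (0.00326), and regulatory T cells without the trend (0.0407). A filter on all 4 arrays brought IL-2 and STAT5 signalling (0.0358), type 3 immunity (0.0358), B cells (0.0228), small intestinal enterocytes (0.0484) and distal Hox genes (0.045) past the threshold.

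Lists that had not passed turned direction as follows. Quantile normalization turned interferon-stimulated (adjusted p = 0.810) and Y-linked genes (0.871). Dropping the filter turned type 2 (0.680), monocyte (0.413), mast cell (0.686), colonocyte (0.931), fibroblast (0.629), AP-1 (0.514), immediate early (0.987) and Y-linked genes (0.629). Type 2 also turned with a filter on all arrays (0.965) and without the trend (0.964), AP-1 with the block (0.899) and monocytes with fry (0.975). Without 1 array, ranges of lists that turned were type 2 0.603 to 0.899, plasma cell 0.0727 to 0.910, monocyte 0.00432 to 0.803, mast cell 0.000284 to 0.545, fibroblast 0.000507 to 0.123, endothelial 0.0052 to 0.889, Y-linked 0.327 to 0.576, interferon-stimulated 0.0263 to 0.759, AP-1 0.173 to 0.871, immediate early 0.0182 to 0.803 and distal Hox 1.2e-07 to 0.486. Log2 differences ranged from -0.145 to 0.0841 for Cd4, -1.80 to 1.67 for Mcpt1 and -2.61 to 0.26 for Hoxb13.

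Of 70 named genes past an unadjusted p of 0.05, 52 stayed past it without any 1 array and 59 under every change of processing that tested them. The exocrine pancreas and Y-linked lists could not be tested in 1 alternative each.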

Other observations

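The groups of genes in this part were chosen after the data were seen, and so were the tests on dim probes, sex and the stretch of colon. The MHC class II and antigen presentation group rose, with all 12 genes higher in both the female and the male pair (median 0.67, camera adjusted p = 4.08e-14). Of 47 histone genes, taken by the form of their names alone, 34 were higher and 13 lower (median 0.58, adjusted p = 8.12e-11). Genes of histone H2B were among the lower, such as Hist1h2bb (-0.30) and Hist3h2ba (-0.40), though Hist2h2bb was higher (0.90). Some probes of the 47 genes overlap on the genome, so the 47 are not all separate measurements. Of 14 tissue kallikrein genes chosen 9 were tested, and all 9 were lower in both pairs (median -0.69, adjusted p = 3.16e-11). Their differences were alike, from -0.79 (Klk1b21) to -0.44 (Klk1b26). Whether their probes measure separate transcripts was not tested, so the 9 may not be separate measurements. Cytochrome P450 genes of families 2c and 2d were lower in 13 of 13 cases, 11 of them in both pairs (median -0.34, adjusted p = 4.57e-07). These p values do not allow for the choice of the groups, and with an estimated correlation the adjusted p was 0.294 for MHC class II, kallikrein and P450 genes and 0.300 for histones. The smallest unadjusted p of all genes belonged to Irg1, now named Acod1, which makes the macrophage metabolite itaconate (log2 difference 2.10 ± 0.15, adjusted p = 0.373). Ido1, an interferon-induced enzyme of tryptophan breakdown, followed at 1.56 ± 0.12 (adjusted p = 0.373). With sex as a block both passed the adjusted threshold (adjusted p = 0.0409). Both lay outside the naming rule and were chosen after their values were seen.

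Interferon-induced genes went both ways, and a hypothesis is that the mutant colon carried a response weighted to interferon gamma over type I interferon. It was tested on genes of either kind that are on no fixed list. Of 11 induced by interferon gamma all were higher (median 0.60), and of 13 induced by type I interferon 12 were lower (median -0.15). The difference of medians was 0.76 (95% bootstrap interval over genes 0.58 to 1.18), consistent with the hypothesis. Camera gave these lists adjusted p of 8.96e-07 and 0.0168, and adjusted p = 0.294 and 0.456 with an estimated correlation. The genes of these and the following lists were picked after the pattern was seen and after genes with small p had been looked at, so the test is not independent, and genes are not independent replicates. A second hypothesis was that the lower T cell signal came from cytotoxic and intraepithelial lymphocytes rather than helper T cells. The difference of medians between 5 genes of the first kind (adjusted p = 0.780) and 8 of the second (adjusted p = 0.128) was 0.0296 (interval -0.39 to 0.82), which leaves it open.

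The lower smooth muscle and adipocyte signals may reflect less outer tissue in the mutant samples, such as muscle wall or attached fat, in place of a change within those cells. Less muscle wall should also lower other muscle genes and the enteric neurons and glia lying in it. Lists of genes on no fixed list had medians of -0.35 for muscle (interval -0.50 to -0.19) and -0.44 for neurons and glia (-0.52 to -0.25), with camera adjusted p of 0.000187 and 0.000209, and adjusted p = 0.294 for both with an estimated correlation. Both medians lay below the bound of -0.3 set for this, but both intervals crossed it. Of the lists fixed in advance for the same cells, muscle had a median of -0.59. Neurons and glia had -0.21 (-0.37 in the female pair, -0.10 in the male pair), above that bound. The abundant adipocyte genes had a median of -0.42 (interval -0.72 to -0.38, adjusted p = 0.000243, and 0.294 with an estimated correlation) against a bound of -0.5, so less tissue and lower expression, including a difference that follows genotype, cannot be told apart. Of these 11 genes 9 were lower, while Pparg and Pnpla2, with control means of 4.13 and 3.93, differed by 0.03 and 0.04. How far other colon cells express the 11 genes was not tested, so their median cannot decide on attached fat.

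That 46 genes passed with a block and 0 without one may come from differences between female and male mice, which add to the spread within each genotype. With crossed blocks, each holding a female and a male, 0 genes passed. That result goes with sex but also with anything else the same-numbered mice share. The stretch of colon sampled is such a factor. Distal Hox genes were higher on the replicate 1 array by a median of 0.93 in one genotype and 2.65 in the other, and Hoxb13 lay at 4.82, 3.52, 4.43 and 1.56 on control 1 and 2 and mutant 1 and 2. Sex and stretch split the arrays the same way and cannot be told apart. The split into female and male arrays gave 3 gene names of the array design past the adjusted threshold (XIST, Xist and Eif2s3y). Of these, XIST and Xist differ in case only and do not count as separate genes. At least 2-fold different with unadjusted p under 0.05 were 357 in this split, against 263 for genotype and 109 for the remaining split. With 3 splits the design cannot give a share under 0.05.

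The largest falls were mostly in dim probes, and a candidate explanation is signal that comes and goes between single arrays. Counting probes well above background on both arrays of one genotype and neither of the other, with a difference over 2 on the log2 scale, gave 67. The female and male split gave 103 and the remaining split 81. The count for genotype was thus no larger than for splits that mix genotypes, and a genotype effect on single probes among them stays untested.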
